A study of Mus musculus with 6 samples.

How the data were processed

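Bulk RNA sequencing was compared between C57BL/6 male mice labelled wild type and mice labelled Otud1-/-, with 3 libraries per genotype. Per the labels' protocols, the RNA came from distal colon next to tumours, after the tumours had been cut away, and was extracted with Trizol; libraries followed standard Illumina protocols. The genome build was mm10, per the submitters' processing notes. The aligner, the read counter, its strand setting and the annotation release are not given in the sources used here. Samples were grouped by the titles and the genotype labels, and the labels do not say whether each library came from a separate animal, so p-values measure the spread between these libraries, which may be partly technical.

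The deposited values are a normalised signal per gene rather than raw counts. In each column every value was a whole multiple of a single step, so dividing by the step gave whole reads for 100% of values (within a tolerance of 0.001 of a read). The steps were the reciprocals of the median-of-ratios size factors that DESeq2 computes from those reads. The deposited signal is therefore called a normalised read count here: reads of the gene divided by the size factor of the library. The table held 21374 genes, each with at least 10 recovered reads over the 6 libraries. Recovered reads per library were 18002560, 19406407 and 19048849 for the libraries labelled wild type 1, 2 and 3, and 18193462, 15300937 and 16172990 for those labelled Otud1-/- 1, 2 and 3. The 10 most abundant genes took 5.69% to 7.56% of a library's reads. Reads carry no molecular identifiers, so counting error is a lower limit of the technical error.

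Gene IDs were matched to GENCODE vM21 (GRCm38) for symbols and coordinates, without the version suffix: 21336 IDs matched, 18829 of them with the same version, and 38 did not. Genes with a normalised read count of at least 1 in at least 3 libraries were tested (21281 genes; 93 were left out). Because the unit is normalised, the test was limma (version 3.58.1, R 4.3.3; lmFit, then eBayes with trend and robust) on log2 of the normalised read count plus a pseudocount of 1, with genotype as the only term, two-sided, and Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05. Fold changes are on the scale of log2(value + 1), which understates changes of genes with few reads. Errors of means are SDs over 3 libraries and errors of log2 changes of single genes are limma's standard errors. Errors of list and block medians were taken over member genes as if independent, so they leave out the spread between libraries. Errors of list means relative to the epithelium list were taken over libraries. The Otud1 values also had an exact two-sided permutation test.

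Before the data were examined, 31 gene lists were fixed for pathways, tissue functions and the cell types that a piece of distal colon may hold, beside a short list of sex-linked genes as a check of the labels. Lists were tested with camera (preset correlation between genes of 0.01) on the same fit, adjusted by Benjamini-Hochberg over the 31 lists. Camera with an estimated correlation and fry were run beside it. The rule for named genes was also fixed then: Otud1, Tfrc and Ireb2; the 10 largest rises and 10 largest falls among called genes whose genotypes did not overlap and whose mean was at least 1, passing over predicted or unnamed symbols and immunoglobulin or T cell receptor segments; and from each list up to 4 members with the smallest p.

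Alternatives fixed at the same time were no filter, a filter at a mean of 5, pseudocounts of 0.1 and 0.01, renewed median-of-ratios scaling, quantile normalisation, limma without trend and robust, sample weights, the replicate number as a block, looser thresholds and the omission of each library in turn. Chosen after the data were seen were count tests on the recovered reads (edgeR 4.0.16 quasi-likelihood test with TMM or median-of-ratios factors, DESeq2 1.42.0, limma-voom), scaling to total reads or to the epithelium list, and the omission of the libraries labelled wild type 1 and Otud1-/- 1 together. The count test with edgeR and TMM called 62 genes, and DESeq2 called 1413.

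The tests were tried on simulated data: negative binomial reads drawn from the means of these genes, with 200 genes changed. In this simulated comparison of 3 against 3 libraries over 20828 genes, limma recovered 46.0% of the 2-fold and 78.0% of the 4-fold changes, none with the wrong sign, and 16 of its 141 calls (11.3%) were unchanged genes, above the nominal 5%. The same data gave 24.9% unchanged genes among DESeq2's calls over 20859 genes and 9.29% among edgeR's over 16605. A simulated list of 20 genes shifted together was called by camera (adjusted p = 1.3e-11 over 20828 genes), and 0 of 30 unchanged lists were. The simulated genes were drawn independently of each other. The result therefore does not give camera's rate of false calls for lists whose genes vary together. In the real data the estimated correlation was 0.86 in the smooth muscle list.

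Without a known strand setting, reads of overlapping genes cannot be told apart. Among named genes that were called, exons overlap those of another annotated gene for Hmga2, Fn1, Zfp286, Synm, Plin4, Ckm, Il1b, Gml2 and Duoxa2. Near-identical relatives may share reads with Gml and Gml2, Ly6i and Ly6g, Saa1, Clca4b, Sirpb1a, Sprr2h and the pseudogene Ak3l2-ps, so their values are uncertain to that extent. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.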

Results

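Male mice received azoxymethane, a carcinogen that acts on the colon, on day 0 at 6 weeks of age, followed by 3 cycles of 4 days of 1.5% dextran sulfate sodium, which injures the colonic epithelium, and 14 days of water. Colon was taken on day 81, at 18 weeks of age. The labels give 3 libraries as wild type and 3 as Otud1-/-, with 15300937 to 19406407 reads assigned to genes in each. Pearson correlations of log2 values lay between 0.968 and 0.977 within the libraries labelled wild type, between 0.963 and 0.972 within those labelled Otud1-/-, and between 0.937 and 0.973 across labels. No pair of libraries was alike within counting error (chi-square per degree of freedom of at least 17.7). On the first principal component (38.8% of the variance) the labels separated, with wild type 1 at -86.5 and Otud1-/- 1 at 83.3, while the remaining libraries lay between -25.8 and 28.2. Xist, which marks female cells, had a normalised read count of at most 4.27 in any library. The Y-linked Uty was present in every library at 267 to 469, so both labels fit male tissue.

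Otud1 itself, which encodes a deubiquitinase, went against the labels: its reads were more abundant in the libraries labelled Otud1-/-. Otud1 (ENSMUSG00000043415.5) is a single-exon gene on the plus strand of chromosome 2, 19657752 to 19660583 in GRCm38. Its normalised read counts were 111, 45.1 and 48.9 in the libraries labelled wild type (mean 68.3 ± 36.8 SD, n = 3) and 141, 150 and 208 in those labelled Otud1-/- (166 ± 36.5 SD, n = 3). The change was 1.37 ± 0.35 (SE) on the log2 scale with an adjusted p of 0.0934 (limma, Benjamini-Hochberg), so Otud1 was not called, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. It passed with DESeq2 (adjusted p = 0.0142), with sample weights (0.0442), after scaling to the epithelium list (0.01) and without wild type 1 and Otud1-/- 1 (0.00495), within a range of 0.00495 to 0.258 over all settings. Which part of the gene was deleted is not stated, and a count over the whole exon does not show whether the coding sequence is intact. All directions below are therefore those between the libraries as labelled, and a change is given as Otud1-/- minus wild type by label.

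The comparison of the labels asks which transcripts differ in tumour-adjacent colon between the genotypes. In the libraries labelled Otud1-/-, the defence genes Saa1 and Duoxa2, the mucus gene Fcgbp, Nos2 and Ido1 fell, while the contractile genes Myh11 and Myl9 rose. The transferrin receptor gene Tfrc and the iron exporter gene Slc40a1 also fell. Of 21281 genes tested, 202 were called (limma, adjusted p under 0.05), 60 higher and 142 lower, and 134 of them changed at least 2-fold, 44 higher and 90 lower. In all 202 the genotypes did not overlap, as in 26.3% of all tested genes, where chance gives 10%. The count depended on the test and on single libraries: DESeq2 called 1413 genes (198 of the 202 among them), edgeR 62 (all 62 shared and in the same direction) and limma without trend and robust 0 (3499 genes at an unadjusted p under 0.05). It was 35, 11 and 10 without wild type 1, 2 and 3 and 333, 340 and 114 without Otud1-/- 1, 2 and 3.

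The split between higher and lower genes depended on the scaling, the test and single libraries. With the deposited scaling, 70.3% of called genes were lower, against 60.1% after quantile normalisation, 24.8% after scaling to total reads, which moved the median of all genes by 0.20 on the log2 scale, and 13.2% after scaling to the epithelium list, which moved it by 0.31. With the deposited scaling kept, the share was 56.8% without Otud1-/- 1 and 48.7% without wild type 1 and Otud1-/- 1, and DESeq2 on the recovered reads gave 52.7%. The share rose to 85.7%, 90.9% and 90.0% without wild type 1, 2 and 3, and to 81.5% and 79.8% without Otud1-/- 2 and 3. On the recovered reads, edgeR with TMM gave 75.8% and limma-voom 78.0%. Relative to the median of all genes after scaling to total reads, the smooth muscle list stood at 1.05 and the goblet cell list at -0.82, close to their values with the deposited scaling. This closeness is no test. Scaling by a single factor per library shifts all genes alike apart from the pseudocount, so it follows by construction. The same holds for all values below that are given relative to that median. Of 39 named genes that were called, 37 kept their call after scaling to total reads, 36 after scaling to the epithelium list and 32 after quantile normalisation, and none changed direction. Without wild type 1, 2 or 3 the call was kept by 11, 5 and 5 of the 39, and without Otud1-/- 1, 2 or 3 by 34, 31 and 24. Fcgbp, Fer1l6, Saa1 and Ido1 kept it in all 6 of these fits, and Hsd17b14 in 0.

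**Figure D1:**
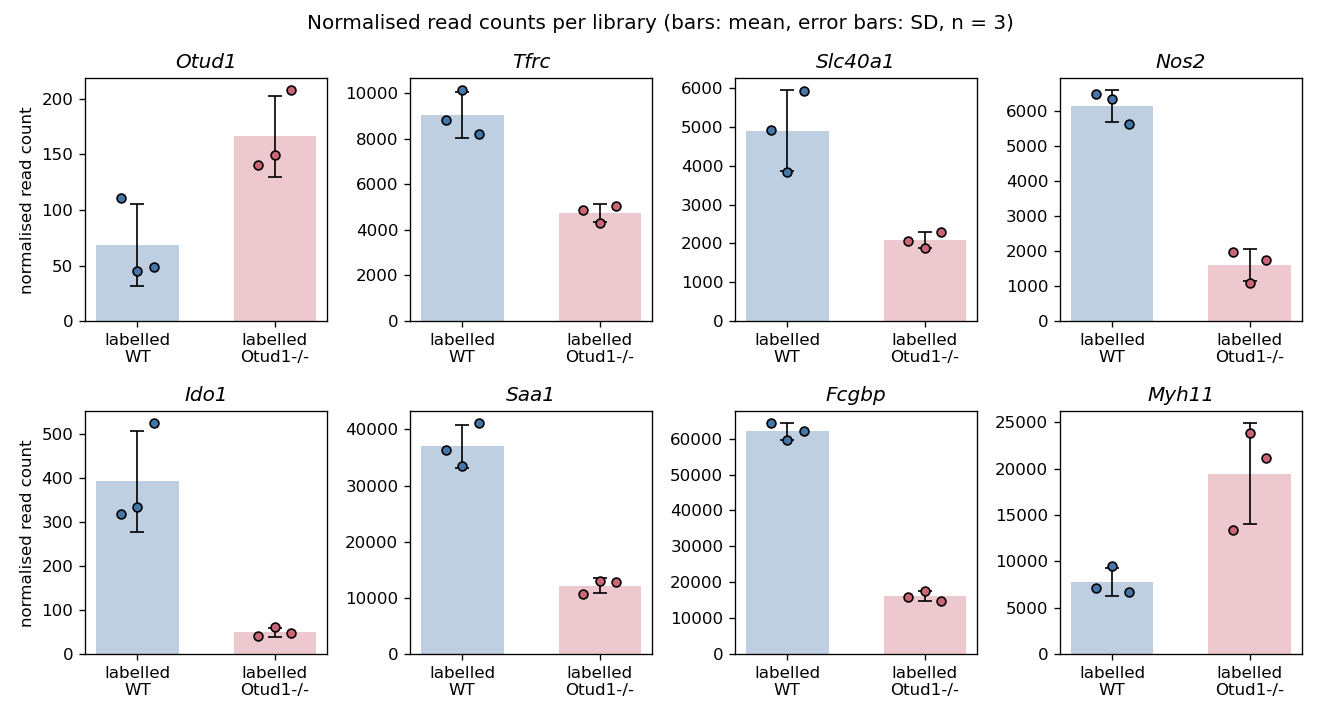
Normalised read counts (vertical axis, from 0) of 8 genes in each library, grouped by genotype label (horizontal axis); points are libraries, bars the means and error bars the SD over 3 libraries. In every panel the points of the labels do not overlap: Otud1 and Myh11 lie higher in the libraries labelled Otud1-/- and the other genes lower, with Otud1 not called (limma, adjusted p = 0.0934).

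Of the iron genes, the importer Tfrc and the exporter Slc40a1 fell, and the iron regulatory protein gene Ireb2 did not pass the test. Tfrc (chromosome 16, 32608920 to 32632794) had 9039 ± 993 normalised reads (SD, n = 3) in the libraries labelled wild type and 4738 ± 384 in those labelled Otud1-/-, a log2 change of -0.93 ± 0.13 SE (limma, Benjamini-Hochberg adjusted p = 0.0188). Slc40a1, which encodes ferroportin (chromosome 1, 45908068 to 45926523), had 4906 ± 1050 against 2082 ± 206, a change of -1.22 ± 0.16 SE (limma, adjusted p = 0.0177). Ireb2 had 1132 ± 80.6 against 1173 ± 149 (change 0.05 ± 0.13 SE, limma, adjusted p = 0.874). Of 22 measured members of the iron list, 2 were lower and none higher over all genes. When adjusted over the list alone 2 were lower and 1 higher, the metal transporter Slc39a8 (0.83). The list was lower (median -0.26, camera, adjusted p = 0.00392), with an adjusted p of 0.373 with an estimated correlation. Its median was 0.06 after scaling to the epithelium list, which is -0.27 relative to the median of all genes. Tfrc lost its call without wild type 1, 2 or 3 (limma, adjusted p = 0.0843, 0.0944 and 0.0865), after quantile normalisation (0.0928) and after scaling to the epithelium list (0.0744). Slc40a1 lost it without wild type 1 or 3 (limma, adjusted p = 0.0789 and 0.0964), and the list without Otud1-/- 2 (median -0.18, camera, adjusted p = 0.056) and after quantile normalisation (0.0536).

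Some epithelial defence and mucus genes fell. Saa1, an acute-phase apolipoprotein made by inflamed epithelium, went from 37011 ± 3841 to 12203 ± 1320 normalised reads (log2 change -1.60 ± 0.14 SE, limma, adjusted p = 0.00284). The hydrogen peroxide-producing oxidase Duox2 changed by -1.03 and its maturation factor Duoxa2 by -1.27, with Sprr2h at -2.27. In the defence list 4 of 17 measured members were lower and none higher over all genes, and 11 were lower and none higher when adjusted over the list alone. The list median was -1.03 (camera, adjusted p = 1.97e-05; adjusted p = 0.175 with an estimated correlation). Members went both ways, 4 with positive and 13 with negative changes. In the goblet cell list all 13 members had negative changes (median -0.81, camera, adjusted p = 8.4e-09; adjusted p = 0.107 with an estimated correlation). The mucus protein gene Fcgbp fell from 62044 ± 2307 to 16098 ± 1437 (log2 change -1.95 ± 0.13 SE, limma, adjusted p = 0.000891) and Fer1l6 by 1.74 on the log2 scale. These were the 2 members called over all genes, against 11 lower when adjusted over the list alone, among them the mucin gene Muc2 (-0.98) and Zg16 (-2.12). The epithelium list, which holds pan-epithelial markers, was itself lower in the same libraries (median -0.40, camera, adjusted p = 0.000243; adjusted p = 0.622 with an estimated correlation). None of its 15 members was called over all genes, 4 were lower when adjusted over the list alone, and the call was lost after quantile normalisation (median -0.06, adjusted p = 0.764). The median was -0.66 without Otud1-/- 2.

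Of the inflammatory mediators, Nos2, Ccl20 and Il1b fell. Nos2, the inducible nitric oxide synthase, had 6156 ± 455 normalised reads in the libraries labelled wild type and 1609 ± 455 in those labelled Otud1-/- (log2 change -1.98 ± 0.21 SE, limma, adjusted p = 0.00857). Ccl20, a chemokine of epithelium, changed by -1.32 and Il1b by -0.81. These were the 3 of 25 members of the NF-kB and cytokine list that were lower over all genes, and 7 were lower and 1 higher when adjusted over the list alone (Il23a, 1.90, named after its value was seen). The list median was -0.36 (camera, adjusted p = 0.00048; adjusted p = 0.592 with an estimated correlation). It was -0.58 without Otud1-/- 1, -0.66 without wild type 1 and Otud1-/- 1, -0.16 after scaling to total reads and -0.06 after scaling to the epithelium list. Relative to the epithelium list, the mean of the list differed between the labels by -0.07 ± 0.39 SE (exact permutation p = 0.9). Ido1, which encodes a tryptophan-degrading enzyme induced by interferon gamma, fell by 2.95 on the log2 scale (393 ± 115 to 49.4 ± 10.5).

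The antigen presentation, macrophage and B cell lists were lower with no member called over all genes, while the T and NK cell and neutrophil lists were not called. The antigen presentation list (median -0.93, camera, adjusted p = 2.14e-08; adjusted p = 0.592 with an estimated correlation) had 18 of 19 members with negative changes, 0 called over all genes and 11 lower when adjusted over the list alone, such as H2-D1 (-1.02) and Irf1 (-0.79). Macrophage and monocyte genes (median -0.64, camera, adjusted p = 4.15e-07; adjusted p = 0.354 with an estimated correlation) had 15 of 15 negative, 0 called over all genes and 12 lower when adjusted over the list alone, among them Itgam (-1.24) and Lyz2 (-0.75). B and plasma cell genes (median -0.91, camera, adjusted p = 0.000126; adjusted p = 0.622 with an estimated correlation) had 15 of 15 negative and 0 called by either adjustment. Their median was -0.55 without wild type 1 and -0.59 without Otud1-/- 1, and their call was lost without wild type 1 and Otud1-/- 1 together (median -0.17, camera, adjusted p = 0.328), and the antigen presentation median was then -0.38. T and NK cell genes missed the threshold (median -0.40, camera, adjusted p = 0.0561), with 18 of 20 negative and 0 called by either adjustment. Their value depended on single libraries: the median was 0.00 without wild type 1 (adjusted p = 0.944), -0.11 without Otud1-/- 1 (0.387) and 0.31 without wild type 1 and Otud1-/- 1 together (0.0857). The list passed as lower without wild type 2 (0.0287), wild type 3 (0.000664) or Otud1-/- 2 (0.0107) and after scaling to total reads (0.00578), to the epithelium list (0.00333) or by quantiles (0.0119). The neutrophil list was not called (median 0.04, mean -0.03, camera, adjusted p = 0.475), although Ly6g fell by 1.66 on the log2 scale, with 0 higher and 1 lower over all genes and 1 higher and 3 lower when adjusted over the list alone. It passed as lower without Otud1-/- 1 (camera, adjusted p = 0.0426) and without wild type 1 and Otud1-/- 1 together (0.00329).

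Contractile genes were higher. All 15 smooth muscle members had positive changes between the labels (median 1.06, camera, adjusted p = 7.82e-10; adjusted p = 0.592 with an estimated correlation), 4 of them called over all genes and 15 when adjusted over the list alone. Myh11, the smooth muscle myosin heavy chain, went from 7782 ± 1525 to 19467 ± 5460 normalised reads (log2 change 1.30 ± 0.23 SE, limma, adjusted p = 0.0492), Synm changed by 1.32, Myl9 by 1.24 and Cald1 by 0.90. Of the 6 fits without single libraries, Myh11 and Cald1 kept their call in 1 and Synm and Myl9 in 2. The smooth muscle list kept its camera call in all 6. The epithelium list changed the opposite way between the labels (median -0.40), but not library by library. Its mean (log2) was 14.06, 14.01 and 14.19 in wild type 1, 2 and 3 and 13.58, 14.05 and 13.69 in Otud1-/- 1, 2 and 3. Otud1-/- 2, which lay within the wild type range, had the highest smooth muscle mean (12.1, against 11.2 and 11.8 in Otud1-/- 1 and 3). Skeletal muscle genes were higher too (median 0.85, camera, adjusted p = 0.00177; adjusted p = 0.326 with an estimated correlation), with Ckm, muscle creatine kinase, the 1 member of 9 called over all genes (1.63) and 2 higher when adjusted over the list alone. The skeletal muscle list mean (log2) was 4.01 in the libraries labelled wild type and 4.85 in those labelled Otud1-/-. Much of its change therefore rests on genes with few reads. The enteric neuron and glia list was called at the edge of the threshold (median 0.40, camera, adjusted p = 0.047; adjusted p = 0.694 with an estimated correlation) with 0 members called over all genes and 1 higher and 1 lower when adjusted over the list alone. Its call was lost without wild type 1 (0.105), wild type 3 (0.137), Otud1-/- 2 (0.148) or Otud1-/- 3 (0.311), after scaling to total reads (0.0626) and after quantile normalisation (0.15).

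Stem cell and Wnt target genes were the list with the largest median change, 1.69, yet none of the 20 members was called over all genes or when adjusted over the list alone (camera, adjusted p = 2.18e-05; adjusted p = 0.622 with an estimated correlation). Changes were positive for 19 of 20, with Smoc2 at 1.96 and, named after their values were seen, Notum at 3.81 and Lgr5 at 3.35, against a spread within labels that Smoc2 shows: 189, 535 and 566 in the libraries labelled wild type and 2865, 973 and 1218 in those labelled Otud1-/-. Without wild type 1 and Otud1-/- 1 the median was 0.66 (camera, adjusted p = 6.95e-05). Proliferation genes had a median of 0.43 (camera, adjusted p = 0.00011; adjusted p = 0.622 with an estimated correlation), with 18 of 20 positive, 0 called over all genes and 8 higher when adjusted over the list alone, including Mcm2 (0.75) and Mcm6 (0.72). Their median was 0.26 without wild type 1 and Otud1-/- 1 (camera, adjusted p = 0.0428).

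**Figure D2:**
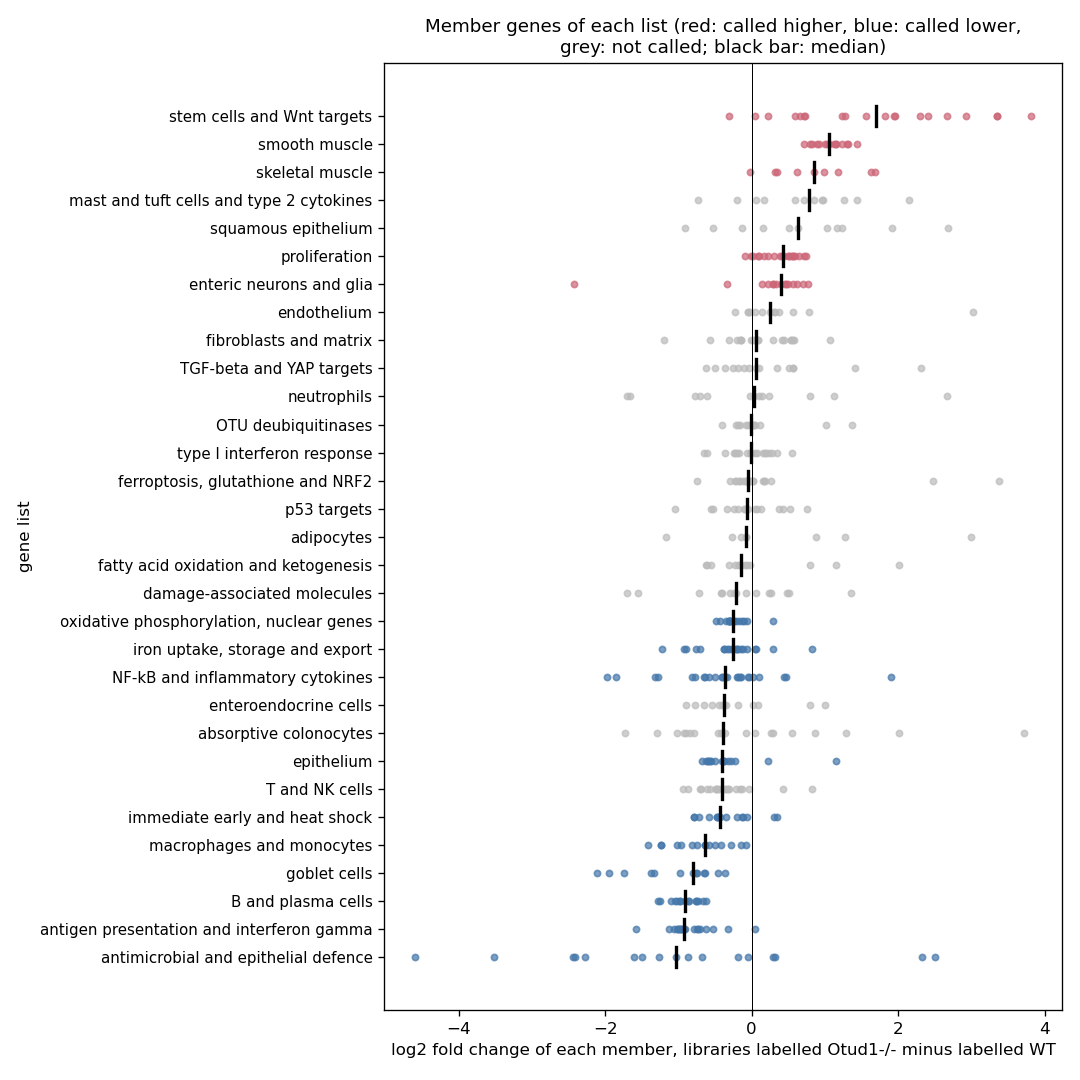
Log2 change of every measured member (points, horizontal axis, libraries labelled Otud1-/- minus labelled wild type) of the 31 gene lists (vertical axis), with the list median as a black bar. Red and blue mark the 5 lists called higher and the 10 called lower by camera with a preset correlation, grey the others. With an estimated correlation 0 lists passed. Among the called lists the medians of the iron and oxidative phosphorylation lists turn positive after scaling to the epithelium list (0.06 in each). That scaling moved the median of all genes by 0.31, and relative to that median these lists stood at -0.27 and -0.26. It shifts all genes of a library alike, so these relative values follow from the deposited scaling by construction.

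Energy metabolism genes shifted little. Nuclear oxidative phosphorylation genes were lower (median -0.26, 17 of 18 negative, camera, adjusted p = 0.000249; adjusted p = 0.622 with an estimated correlation) with 0 called by either adjustment. Their call was lost after quantile normalisation (median -0.01, camera, adjusted p = 0.983) and after scaling to the epithelium list (median 0.06, camera, adjusted p = 0.132). The latter median is -0.26 relative to the median of all genes. Fatty acid oxidation genes were not called as a list (median -0.15, mean 0.05, camera, adjusted p = 0.223). Their median was 0.06 after scaling to total reads, which is -0.16 relative to the median of all genes. Of the 15 members 3 were lower when adjusted over the list alone, among them Cpt1a (-0.56) and Acadl (-0.63). Immediate early and heat shock genes were lower (median -0.44, camera, adjusted p = 0.0154; adjusted p = 0.622 with an estimated correlation), 13 of 15 negative, with 0 called over all genes and 2 lower when adjusted over the list alone. That call was lost without wild type 2 (0.0579) or Otud1-/- 1 (0.0887), without wild type 1 and Otud1-/- 1 together (0.143), and after quantile normalisation (0.255). Of the 15 lists called with the preset correlation, 0 passed with an estimated one and 3 passed with fry, which asks whether the genes of a list move one way: goblet cells (adjusted p = 0.00346), defence (0.0127) and skeletal muscle (0.0175).

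The remaining lists were not called by camera. Their medians were 0.78 for mast and tuft cells (adjusted p = 0.0853), 0.25 for endothelium (0.138), 0.63 for squamous epithelium (0.157), -0.37 for enteroendocrine cells (0.201). Medians were -0.21 for damage-associated molecules (0.223), 0.06 for fibroblasts and matrix (0.319), -0.08 for adipocytes (mean 0.43; 0.342). They were -0.06 for p53 targets (0.475) and -0.39 for absorptive colonocytes (mean -0.01, camera, adjusted p = 0.475). Ferroptosis, glutathione and NRF2 genes had -0.05 (mean 0.22, camera, adjusted p = 0.626) and OTU deubiquitinases 0.00 (mean 0.11, camera, adjusted p = 0.777). The type I interferon response had -0.01 (0.777) and TGF-beta and YAP targets 0.06 (0.826). Some passed with other settings: mast and tuft cells without wild type 2 (0.0168) or Otud1-/- 3 (0.00571), squamous epithelium without Otud1-/- 3 (0.0362), type I interferon genes (median 0.27) without Otud1-/- 1 (0.0426), and endothelium without Otud1-/- 1 (0.0161). Endothelium also passed without wild type 1 and Otud1-/- 1 (0.00693) or after scaling to the epithelium list (0.0453). Damage-associated molecules passed without wild type 1 and Otud1-/- 1 (0.0247). The medians of the OTU, ferroptosis, interferon, p53 and adipocyte lists turn positive after scaling to total reads or to the epithelium list, and that of damage-associated molecules after the latter. These scalings moved the median of all genes by 0.20 and 0.31. Relative to that median the first lists stood at -0.09 to -0.01 and damage-associated molecules at -0.22, which follows from such scaling by construction. Members called over all genes included Fn1 of the matrix list (fibronectin, 1.07) and the lipid droplet gene Plin4 of the adipocyte list (1.28). When adjusted over the list alone, 3 matrix members (Col4a1 and Col4a2 beside Fn1) and 2 adipocyte members (Cfd beside Plin4) were higher. Cfd had 0 normalised reads in every library labelled wild type and at most 11.9 in those labelled Otud1-/-. Its rise therefore rests on few reads. By the same adjustment 1 p53 target (Fas) was lower, 1 enteroendocrine member was higher (Scg2) and 1 lower (Tph1). Of the damage-associated molecules 1 was higher (Hsp90aa1) and 4 were lower, among them Tlr4 and S100a8. Otud1 was the 1 OTU member to pass (adjusted p = 0.0486). There were 0 such members in the mast and tuft cell, endothelium, squamous, ferroptosis, interferon and TGF-beta lists. The sex-linked genes Uty, Ddx3y, Kdm5d and Eif2s3y were not called, with changes of -0.45, -0.15, -0.10 and -0.08, the last 3 positive after scaling to total reads.

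Among the 10 largest rises were genes of peptide signalling and growth. Npy2r and Npy4r, receptors of the neuropeptide Y family, rose by 3.46 and 1.67 on the log2 scale, and Tacr2, a tachykinin receptor, by 1.80. Igfbp2, an insulin-like growth factor binding protein, went from 62.6 ± 22.7 to 533 ± 198 normalised reads (log2 change 3.06 ± 0.33 SE, limma, adjusted p = 0.00857), and the chromatin protein gene Hmga2 from 23.5 ± 6.89 to 114 ± 58.4 (2.15 ± 0.40 SE, adjusted p = 0.0477). Gulo (3.62), Hsd17b14 (3.23), Zfp286 (2.48) and the matrix gene Thbs2 (1.68) were also in this group. Npy2r and Hsd17b14 were at most 2.04 and 2.11 normalised reads in any library labelled wild type, so their folds rest on few reads. Npy2r kept its call in 1 of the 6 fits without single libraries. The 10 largest falls held Clca4b, which went from 68043 ± 7147 to 9166 ± 4421 (-3.04 ± 0.43 SE, limma, adjusted p = 0.0457), Ido1, the GPI-anchored Ly6 relatives Gml (-2.73), Gml2 (-2.87) and Ly6i (-2.38), the receptor gene Sirpb1a (-2.69) and the pseudogene Ak3l2-ps (-2.36). They also held Myot, which encodes a Z-disc protein of muscle and fell by 3.35 on the log2 scale (88.7 ± 20.4 to 8.17 ± 3.72) while the muscle lists were higher. Spink6 (-3.33) and Lce3b (-3.14) were at most 2.02 and 1.12 normalised reads in any library labelled Otud1-/-, so their folds rest on few reads.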

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

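Count tests on recovered reads, scaling to total reads or to the epithelium list, and the joint omission of wild type 1 and Otud1-/- 1 were chosen after the data were seen. The cause of the differences was not tested unless stated. The 202 called genes (60 higher, 142 lower in the libraries labelled Otud1-/-) became 122 (32 and 90) with a filter at a mean of 5, 118 (31 and 87) and 110 (29 and 81) with pseudocounts of 0.1 and 0.01, 153 (61 and 92) after quantile normalisation, 0 (0 and 0) with limma without trend and robust, where 3499 genes had an unadjusted p under 0.05, and 564 (219 and 345) with sample weights. A threshold of 0.1 gave 877 (350 and 527) and an unadjusted p under 0.05 gave 4143 (2021 and 2122), by their construction. On recovered reads edgeR called 62 (15 and 47) with either scaling, DESeq2 1413 (669 and 744) and limma-voom 59 (13 and 46). Scaling to total reads gave 416 (313 and 103), scaling to the epithelium list 881 (765 and 116) and omission of wild type 1 and Otud1-/- 1 gave 394 (202 and 192). Leaving out single libraries gave 10 to 340 genes in total, 1 to 144 higher and 9 to 277 lower, with the lowest count without wild type 3 and the highest without Otud1-/- 2. No filter gave 204 genes and renewed median-of-ratios scaling 202.

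With the replicate number as a block, 18 genes were called (0 higher and 18 lower; 2968 at an unadjusted p under 0.05, and edgeR without the block called 15 higher), and 15 lists. The numbers did not pair the samples: deviations of same-numbered libraries from their group means correlated at -0.26, -0.10 and -0.09, and no library correlated best with its own number.

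The 15 called lists became 0 with an estimated correlation between genes and 3 with fry, and stayed between 11 and 17 elsewhere, 14 to 17 without single libraries. Otud1 was higher in every setting, at 1.14 to 1.78 without single libraries; it passed the threshold with sample weights (1.59), DESeq2 (1.29), scaling to the epithelium list (1.68) and without wild type 1 and Otud1-/- 1 (1.89).

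Among 850 values of the 39 named called genes, 539 kept their call, 311 lost it with the same direction and 0 reversed. Among 2304 values of uncalled named genes, 129 passed and 20 reversed, all uncalled under both settings. The reversed changes were, for Ireb2, between -0.0512 and 0.125 without single libraries and -0.0300 without wild type 1 and Otud1-/- 1. After scaling to total reads they were Otud6b 0.0469, Ddx3y 0.0620, Kdm5d 0.11 and Eif2s3y 0.13, and after scaling to the epithelium list Otud5 0.11, Otud6b 0.15, Sat1 0.0262, Txnrd1 0.0855, Lipe 0.0519, Uqcrc2 0.0108, Ddx3y 0.17, Kdm5d 0.22 and Eif2s3y 0.24. After quantile normalisation they were Txnrd1 0.0186 and Eif2s3y 0.00289, without wild type 1 and Otud1-/- 1 Ddx3y 0.0189, and for Eif2s3y without single libraries -0.148 to 0.0212. Of 558 list values, 526 were the same, 16 lost and 15 gained a call, and the type I interferon list reversed without Otud1-/- 1 (median 0.27, camera, adjusted p = 0.0426; range without single libraries -0.21 to 0.27). Depth limits what can be said of genes with few reads, whose changes depend on the pseudocount.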

Other observations

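The tests of the Otud1 reads, of the epithelial share, of unequal tumour tissue and of the Ly6 block, the omission of single libraries from the means relative to the epithelium list, and the genes named in the next 2 paragraphs, were chosen after the values were seen. Some genes of glycolysis and the response to hypoxia fell in the libraries labelled Otud1-/-. Pgk1 had 17035 ± 457 normalised reads (SD, n = 3) in the libraries labelled wild type and 9809 ± 609 in those labelled Otud1-/- (log2 change -0.80, limma, Benjamini-Hochberg adjusted p = 0.0248), Hk2 changed by -1.05, Pdk1 by -0.70, Ak4 by -2.32 and Epas1 by -0.79. Of 24 other measured gene IDs of such genes, 20 had negative changes and 0 were called. Their median was -0.53 ± 0.12 SE over gene IDs (camera, p = 9.49e-07, and p = 0.167 with an estimated correlation). Other scalings were not run for this list.

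On chromosome 15, between 74813452 and 75222661 in GRCm38, 7 genes of the Ly6 family block were called and all 7 were lower: Gml, Gml2, Ly6i, Ly6a (-1.06), Ly6c1 (-2.07), Ly6g and BC025446 (-1.42), out of 13 called on the chromosome. The 8 other measured genes of the block had a median change of -0.74 ± 0.29 SE over genes, 7 of them negative. From the mitochondrial genome 4 genes were called and higher, mt-Rnr1 (1.21), mt-Rnr2 (1.12), mt-Tp (0.81) and mt-Nd6 (0.76), while mt-Co1 was not called (0.45, limma, adjusted p = 0.209). All 12 immunoglobulin segments among the 202 called genes were lower.

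Otud1 reads were higher in the libraries labelled Otud1-/-, where a deletion of the whole exon would leave few. A single swapped pair of libraries is argued against, since 0 libraries lay on the other label's side. An exchange of all labels remains open, and so does a deletion that spares most of the exon. The libraries labelled wild type also held Otud1 reads (105, 48 and 48 recovered reads). An exchange alone would therefore not account for the reads if the whole exon were deleted. No annotated exon of another gene overlaps the Otud1 exon (0 found), which argues against reads of an overlapping annotated gene. Whether a larger muscle share carrying Otud1 reads contributes was not settled. The Otud1 change exceeded the smooth muscle median by 0.32, but its SE of 0.35 is too wide for this to decide. In the libraries labelled wild type, Otud1 was 111, 45.1 and 48.9 at smooth muscle list means (log2) of 10.6, 10.7 and 10.6. In those labelled Otud1-/- it was 141, 150 and 208 at means of 11.2, 12.1 and 11.8. A change of the Otud1 locus that also moves neighbouring genes is a candidate explanation too. Of the 2 nearest measured genes on each side by start position, 1 of 4 was called, against 0.949% of all tested genes. The called gene was Msrb2 (1.49 ± 0.26 SE, limma, adjusted p = 0.0413), 263 kb away.

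By camera with the preset correlation, though in no list with an estimated one, smooth muscle genes were higher while epithelial, defence, macrophage, B cell and antigen presentation genes were lower, and T and NK cell, neutrophil, mast and tuft cell and type I interferon genes were not called. A smaller epithelial share alone would raise the genes of every other cell type, yet the macrophage median lay below the smooth muscle median (difference -1.70). Their errors over member genes (SE 0.13 and 0.07) leave out the spread between libraries. By library, the macrophage list mean (log2) was 8.70 to 9.04 in those labelled wild type and 8.01 to 8.34 in those labelled Otud1-/-. The smooth muscle list mean was 10.6 to 10.7 and 11.2 to 12.1. Relative to the epithelium list, the goblet list mean was lower in the libraries labelled Otud1-/- (-0.76 ± 0.19 SE, exact permutation p = 0.1, the smallest possible), by -0.85 to -0.57 without single libraries and beyond 2 SE each time, so dilution of epithelial RNA is argued against as its whole fall. The evidence is weaker for the defence list (-0.68 ± 0.32 SE, exact permutation p = 0.1): the difference was -0.37 ± 0.12 SE without Otud1-/- 2, and within 2 SE of 0 without wild type 2 (-0.60 ± 0.31 SE) or Otud1-/- 1 (-0.79 ± 0.52 SE). A larger piece of muscle wall and an effect of the genotype on the tissue both remain open and were not tested apart.

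Stem cell and Wnt target genes were higher. The list mean (log2) was 6.96, 9.09 and 8.84 in the libraries labelled wild type and 10.8, 9.70 and 9.38 in those labelled Otud1-/-. Its widest gap within a label (2.12, between wild type 1 and 2) was 1.28 times the gap between the labels (1.66). Unequal amounts of tumour tissue left in the pieces are a possible explanation. Such a gap cannot tell tumour tissue from any other source of spread between libraries. Per the labels the tumours had been cut away, which would remove such tissue, and whether any remained was not tested. The same unequal amounts are argued against as the whole fall of the defence list: without wild type 1 and Otud1-/- 1 the defence median kept 104% of its size, and the Wnt median 39.2%. An effect of the genotype stays open and was not tested.

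The 6 libraries can be split in 10 ways, too few for a share under 0.05. The real split called 202 genes with limma, 60 higher and 142 lower, and 1 of the 10 splits, the real one, reached each of these 3 counts, with 0 as the highest of the other splits for each. At an unadjusted p under 0.05 the real split had 4143 genes and the others 400 to 1372, and edgeR called 62 genes in the real split and at most 0 in the others. By camera with the preset correlation the real split called 15 lists, which 2 of the 10 splits reached. The other was wild type 1 with Otud1-/- 2 and 3 against the rest, with 18. Every other split also called lists, from 6 to 18. A list call with this preset is therefore weak evidence for a difference between the labels.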
